A study of Homo sapiens with 12 samples.

How the data were processed

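RNA from the human B-cell lymphoblastic leukemia lines NALM-6 and REH was sequenced after 48 h in RPMI medium with 10% fetal calf serum (media) or in human cerebrospinal fluid (CSF). Each of the 4 combinations of line and medium had 3 libraries, 12 in all, and each library's group and replicate number came from its title, by which libraries are named (NALM-6 media 1). Ranges given "in all" span the adjusted p over a result's alternatives. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy Mini Plus kit, and libraries were dual-indexed stranded TruSeq mRNA libraries. The submitters' processing notes name FastQC, Trimmomatic 0.33, HISAT2 2.1.0, featureCounts, edgeR and the genome build GRCh38, with no role or order. The annotation release and the strand setting of the counting are not given in the sources used here.

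The authors deposited a table of CPM (read counts scaled to a total of 1000000 per library) for 60617 genes, identified by Ensembl gene ID, in the 12 libraries. Each column of CPM values summed to 1000000, so the deposited values were scaled to total reads with no further normalization. Dividing each column by the value of 1 read gave whole numbers for 100% of the values (tolerance 1e-06), and these whole reads summed to between 23412869 and 37146556 per library. A count of 3 reads in a library, the upper limit that 0 reads allows, corresponded to 0.0808 to 0.128 CPM. Limits of this kind and counting intervals (95%) cover counting error only, since reads without molecular identifiers are not independent molecules.

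Gene symbols, biotypes and coordinates (1-based) came from GENCODE release 29 on GRCh38, which held 58542 of the 60617 IDs; the other 2075 were counted in the library totals and carry no symbol here. Because the strand setting is unknown, reads of overlapping genes may have been shared. Among the genes named, this includes FAS and ACTA2, which lie on opposite strands of one locus, ACTA2 with STAMBPL1, and also SULF2 with NCOA3, FUNDC2 with F8, FAM72B with SRGAP2C, DDIT3 with MARS and MBD6, NOP16 with HIGD2A and ARL10, TYMS with ENOSF1, GART with SON, SLC19A1 with COL18A1, PRDM1 with ATG5, TAP1 with PSMB9, CHAF1B with MORC3, ENO2 with LRRC23, MAP1LC3B with FBXO31, TP53I3 with FAM228B and CSF1R with the pseudogene RPL7P1. Antisense RNA genes overlap CDKN1A, ITGB2, TNFAIP3, BTG1, DNTT, TCL1A and IGF2BP1, and GABRA4 overlaps GABRB1. FAM72B and the histone and metallothionein genes also have near-identical copies, so their values are uncertain.

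Because the values are CPM, the main test was limma (3.58.1, in R 4.3.3) on log2(CPM + 1), with an empirical Bayes variance that follows the mean. One model with 4 group means was fitted to all 12 libraries (8 residual degrees of freedom). The 14364 genes with at least 1 CPM in at least 3 libraries were tested, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were CSF minus media in NALM-6, the same in REH, REH minus NALM-6 of these responses (interaction), and REH minus NALM-6 in media. Fold changes are differences of log2(CPM + 1), which understate the change of genes at low CPM. For a gene without reads in a group, folds are given as at least the ratio to 3 reads over the whole group. Where a group held 1 to 3 reads, the ratio carries its 95% counting interval.

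Before the data were examined, 47 gene lists (820 genes), the tests, the alternatives and the rule for naming genes were fixed. Of the lists, 39 with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 39. The 7 smaller marker lists and a list of genes that tell the lines apart were only described. The named genes are, per comparison of CSF with media, the 8 protein-coding genes with the largest rise and the 8 with the largest fall that were called, reached a mean of 5 CPM, and had all 3 CSF libraries on one side of all 3 media libraries. To these were added 6 genes each way called in both lines, 5 each way for the interaction and between the lines in media, up to 4 called members per list and comparison, and each measured gene of the methotrexate list. Y-linked genes and XIST were left out, and results for some genes that the rule names are not reported here.

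Replicate numbers were compared across media by correlating each library's deviations from its group mean. In NALM-6, the same-numbered libraries correlated at 0.36, 0.19 and 0.17, all above the 0.1 set beforehand, so the numbers were taken to pair these libraries. The libraries 2 and 3 correlated across numbers at 0.16 and 0.23, so this pairing rests mainly on the library with the number 1. A model with the replicate number within each line as a block was an alternative.

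The other alternatives were pseudocounts of 0.25 and 5, no filter and a filter at 5 CPM, median-of-ratios scaling, quantile normalization, other variance models, each line alone, each library left out in turn, edgeR (4.0.16, quasi-likelihood test with TMM) and DESeq2 (1.42.0) on the recovered whole reads, camera with an estimated correlation, and fry. Because fry tests a list against no change, the ranges given for lists leave it out. Added after the data were seen were fits without NALM-6 media 1 and REH CSF 3, a correction per library for exonic length and GC content (spline with 5 degrees of freedom), and both with the block or edgeR. In NALM-6 and REH edgeR called 1318 and 1603 genes. Drawing counts for the 14364 genes with 100 genes changed 2-fold and 100 changed 4-fold, limma recovered 28% and 82% in NALM-6 with 9 false calls among 119, and 25% and 83% in REH with 9 among 117. There 40 of DESeq2's 201 calls in NALM-6 and 45 of 190 in REH were false. For the interaction limma recovered 6% and 50% for changes in NALM-6. Libraries like NALM-6 media 1 or REH CSF 3 may alter these rates. Tables and plots used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.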

Results

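RNA-seq compared the leukemia lines NALM-6 and REH after 48 h in media or human CSF, the fluid around the brain and spinal cord. The series title asks whether CSF weakens the effect of methotrexate, an antifolate drug. No label names a drug treatment, so the comparisons concern the medium alone. Each of the 4 groups held 3 libraries, and 17792 to 22486 genes per library had at least 1 read. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Values are mean CPM ± SD with n = 3 per group. Fold changes are log2 differences with their SE, and adjusted p-values are limma's. For each called gene named here, all 3 CSF libraries lay on one side of all 3 media libraries.

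NALM-6 media 1 and REH CSF 3 stood apart from their replicates. Ribosomal protein genes took 21.9% of the reads in NALM-6 media 1, against 8.53% and 7.74% in its replicates, and 10.3% in REH CSF 3, against 5.72% and 6.25%. The genes read were also shorter in both, with a mean exonic length of 4.62 kb and 5.34 kb, compared with 5.98 to 6.34 kb in the other 10 libraries.

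**Figure D1:**
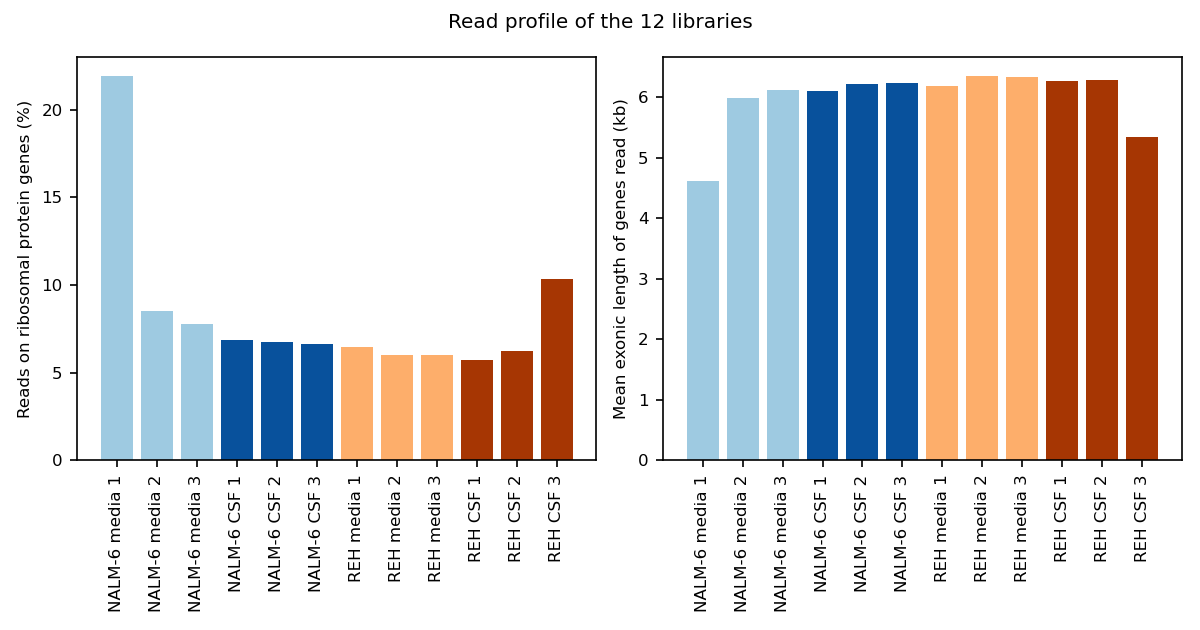
Percent of reads on ribosomal protein genes and mean exonic length (kb) of the genes read, as bars starting at 0 for each of the 12 libraries. NALM-6 media 1 (21.9%, 4.62 kb) and REH CSF 3 (10.3%, 5.34 kb) lie apart from their replicates.

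CSF was first compared with media in NALM-6. The stress-induced transcription factor gene ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777 on GRCh38) rose from 7.39 ± 1.49 CPM in media to 199 ± 4.22 CPM in CSF (log2 4.59, SE 0.14, adjusted p = 4.1e-08). JUN and FOS, which encode subunits of the AP-1 transcription factor, rose from 6.48 ± 3.53 to 131 ± 6.84 CPM and from 0.192 ± 0.139 to 13.1 ± 0.139 CPM. The cell cycle inhibitor gene CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) rose from 157 ± 5.65 to 1324 ± 30.1 CPM (log2 3.07, SE 0.11, adjusted p = 1.3e-07). The mitotic kinase gene PLK1 (ENSG00000166851, chromosome 16, 23677656 to 23690367) fell from 119 ± 32.4 to 38.7 ± 1.54 CPM (log2 -1.56, SE 0.19, adjusted p = 4.0e-04).

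ARRDC4, an arrestin-domain gene regulated with glucose uptake, rose in NALM-6 from 5.37 ± 3.49 to 195 ± 0.933 CPM (log2 5.15, adjusted p = 2.8e-05). The death receptor gene FAS rose from 2.96 ± 1.49 to 39.2 ± 0.26 CPM and PHLDA3 from 4.05 ± 1.98 to 46.0 ± 1.48 CPM (adjusted p = 1.7e-05 and 2.9e-05). The cytokine gene TNF went from 0.289 ± 0.0816 to 13.2 ± 0.794 CPM (adjusted p = 2.5e-07). Among the fallers, CDC20, which activates the anaphase-promoting complex, went from 230 ± 24.6 to 93.2 ± 1.19 CPM (log2 -1.29, SE 0.15, adjusted p = 3.0e-04). PIF1, a DNA helicase gene, and PSRC1, a spindle gene, fell by 1.38 and 1.27 on the log2 scale (adjusted p = 0.00112 and 0.00117). The linker histone gene HIST1H1C (log2 -1.43), MCRIP1 (-1.36), MFSD3 (-1.24) and the mitochondrial protein gene FUNDC2 (-1.20) fell with adjusted p between 0.019 and 0.0483. Without any single NALM-6 CSF library the adjusted p was 0.0545 to 0.0923 for HIST1H1C (log2 -1.30 to -1.55), 0.116 to 0.139 for MCRIP1 (-1.33 to -1.42) and 0.0672 to 0.0753 for FUNDC2 (-1.17 to -1.23). For MFSD3 it was 0.0697 and 0.0757 without CSF 2 or 3 (log2 -1.20 in both). The MCRIP1 call was also lost without any single REH media library or REH CSF 1 or 2. Fits of each line alone ended the calls of HIST1H1C, MCRIP1, MFSD3, FUNDC2 and PIF1. MCRIP1 also lost its call with a pseudocount of 5, no filter, a filter at 5 CPM, median-of-ratios scaling, quantile normalization or a robust variance. Replicate numbers as a block ended the calls of MCRIP1 and FUNDC2. Over their alternatives the adjusted p spanned 1.1e-04 to 0.189 for HIST1H1C, 7.7e-06 to 0.229 for MCRIP1, 2.2e-05 to 0.137 for MFSD3, 2.7e-07 to 0.156 for FUNDC2 and 2.9e-07 to 0.0555 for PIF1.

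In all, 1742 of 14364 genes were called in NALM-6, 1565 higher and 177 lower in CSF, of which 641 and 25 changed at least 2-fold. At an unadjusted p under 0.05 there were 4432 genes. For 46.6% of genes the CSF and media libraries did not overlap, where chance gives 10%. The count was 897, 986 and 865 without NALM-6 CSF 1, 2 or 3, and 864 with the replicate block, which has fewer residual degrees of freedom. The median over all genes was 0.25 with scaling to total reads, 0.03 with median-of-ratios scaling, -0.03 with quantile normalization and 0.05 with edgeR, and 0.09 without NALM-6 media 1. List medians in NALM-6 are therefore to be read against 0.25, or 0.09 without that library. Calls higher and lower in CSF numbered 1073 and 341 with median-of-ratios scaling, 712 and 406 with quantile normalization, and 982 and 336 with edgeR, 1678 and 1703 with DESeq2, and 1350 and 1189 with a correction for exonic length and GC content.

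Most measured p53 target, immediate early and NF-kB target genes rose in NALM-6. Of 21 measured p53 target genes, 18 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 2.08 and a camera adjusted p of 4.3e-14. They included FAS, PHLDA3, CDKN1A and BBC3, which encodes the apoptosis activator PUMA and rose from 6.59 ± 1.69 to 52.9 ± 2.23 CPM (log2 2.85, adjusted p = 6.1e-06). Of 17 immediate early genes, 15 rose (15 adjusted over the list alone; median 1.42, camera adjusted p = 1.9e-11), led by ATF3, JUN, FOS and the zinc finger gene EGR1 (1.4 ± 0.694 to 15.3 ± 0.882 CPM, log2 2.81). Of 18 NF-kB target genes, 13 rose (14 adjusted over the list alone; median 1.57, or 1.94 with the 4 members without media reads at their bound; camera adjusted p = 5.1e-11). Examples were TNF, the receptor gene CD40 (0.0807 ± 0.0642 to 4.54 ± 0.543 CPM), the signaling adaptor gene TRAF1 (log2 2.25) and the adhesion molecule gene ICAM1 (12.7 ± 1.17 to 60.1 ± 2.34 CPM, log2 2.16). These 3 calls hold (adjusted p = 0.0136 for p53 targets, 0.0458 for immediate early genes and 0.0136 for NF-kB targets, with an estimated correlation). With median-of-ratios scaling the medians of p53 targets, immediate early genes and NF-kB targets were 1.80, 1.24 and 1.42. Without NALM-6 media 1 and REH CSF 3 there were 21, 15 and 14 risers.

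Some quiescence, stress response and BCL2 family genes also rose in NALM-6. Of 16 genes linked to quiescence, which slow or block the cell cycle, 8 rose (10 adjusted over the list alone; median 1.05, camera adjusted p = 2.0e-06; adjusted p = 0.226 with an estimated correlation). These included TXNIP (60.6 ± 14.9 to 287 ± 2.74 CPM, log2 2.25) and the antiproliferative gene BTG2 (39.6 ± 6.13 to 189 ± 2.57 CPM, log2 2.24). Without NALM-6 CSF 1, 2 or 3, 5 of the 16 were called. Of 27 genes of the integrated stress response, which ATF4 drives when amino acids or protein folding fail, 9 rose (14 and, lower, 1 adjusted over the list alone; median 0.65, camera adjusted p = 2.2e-04; adjusted p = 0.27 with an estimated correlation). SESN2, TRIB3 and DDIT4, which restrain growth signaling, rose by 2.03, 1.91 and 1.43 (adjusted p = 3.5e-06, 2.3e-05 and 3.7e-04). Of 14 genes of the BCL2 family, which sets the threshold for apoptosis, 5 rose (6 adjusted over the list alone; median 0.63, camera adjusted p = 0.00798; adjusted p = 0.186 with an estimated correlation), among them BBC3, BMF (log2 1.66), PMAIP1 (log2 1.78) and BCL2L1 (log2 0.42), the last named after its value was seen. The BCL2L1 call was lost without any single NALM-6 CSF or REH media library (0.0606 to 0.12), with each line alone, the block, median-of-ratios scaling, quantile normalization, edgeR, DESeq2 and the length and GC correction (0.0595 to 0.523; 6.4e-05 to 0.523 in all). Without NALM-6 CSF 1, 2 or 3 the BCL2 count was 2, 3 and 2, and PMAIP1 lost its call, as with each line alone (6.0e-09 to 0.169 in all). With median-of-ratios scaling the medians were 0.77, 0.36 and 0.36, and without NALM-6 media 1 those of the last 2 lists were 0.42 and 0.39. Fits without both libraries that stood apart gave 13 quiescence, 16 stress response (1 faller) and 13 BCL2 risers.

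Some mitosis and histone genes fell in NALM-6 in CSF, and some G1/S transition and DNA replication genes rose. Of 28 mitosis genes, 5 fell (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00172; adjusted p = 0.35 with an estimated correlation). They included PLK1, CDC20 and the mitotic cyclin gene CCNB1 (171 ± 5 to 79.1 ± 1.98 CPM, log2 -1.10, adjusted p = 1.5e-04), and CCNB2 (log2 -0.52), named after its value was seen. The CCNB2 call was lost without any single library but NALM-6 media 1 or 3 and REH CSF 3 (0.0566 to 0.142), with the block (0.127), and without a filter, with median-of-ratios scaling, a robust variance or each line alone (0.0528 to 0.108; 1.1e-05 to 0.142 in all). The median of this list was 0.08 and its mean -0.05, while camera placed it below the other genes. With median-of-ratios scaling, quantile normalization and edgeR the median was -0.21, -0.16 and -0.28, and without NALM-6 media 1, 2 or 3 it was -0.30, 0.28 and 0.30. The number of mitosis fallers was 9 without NALM-6 media 1. It was 3 without NALM-6 media 2, any single NALM-6 CSF or REH media library or REH CSF 2, and with the block. Of 6 measured replication-dependent histone genes, 4 fell (5 adjusted over the list alone; median -0.67, camera adjusted p = 3.4e-07; adjusted p = 0.0223 with an estimated correlation). HIST1H2BK went from 4.19 ± 0.218 to 1.03 ± 0.161 CPM. Only 6 of 16 listed histone genes were measured, and capture by mRNA libraries was not tested. Without any single NALM-6 CSF library, 2 histone genes were called. Of 16 G1/S cyclin and E2F genes, 5 rose (8 adjusted over the list alone; median 0.91, camera adjusted p = 0.00795; adjusted p = 0.35 with an estimated correlation). CCNE1, which encodes cyclin E1, rose by a log2 of 1.10 and the phosphatase gene CDC25A by 0.83 (adjusted p = 0.0015 and 8.0e-04). The CCNE1 call was lost with median-of-ratios scaling, quantile normalization and edgeR, over a range of 3.0e-09 to 0.105. The list's median was 0.38 without NALM-6 media 1. Its count was 8 without NALM-6 media 1 or 3, and 3 without any single NALM-6 CSF or REH library and with the block. Of 34 DNA replication genes, 5 rose (5 adjusted over the list alone), and the list was not called (median 0.33, camera adjusted p = 0.0621). CDC6 rose by a log2 of 0.84 and CHAF1B by 0.60 (adjusted p = 0.00366 for CHAF1B; lost with the block, median-of-ratios scaling, quantile normalization, edgeR, DESeq2 and the length and GC correction, 1.3e-07 to 0.218 in all). With that correction and the block CDC6 was at 0.0899 (4.1e-09 to 0.0899). The replication count was 10 and 8 without NALM-6 media 1 or 3, 2 without any single NALM-6 CSF library and 1 with the block. The replication list was called without NALM-6 media 1 (adjusted p = 0.00253, 6.3e-05 to 0.628 in all). With median-of-ratios scaling the medians of the histone, G1/S and replication lists were -0.81, 0.64 and 0.03. Leaving out both libraries gave 17 mitosis fallers of 28 (2 risers) and 23 replication risers of 34 (1 faller).

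Lists of ribosome production, respiratory chain and heat shock genes lay below the other genes in NALM-6 in CSF. Of 26 genes linked to MYC and ribosome assembly, 3 fell (5 adjusted over the list alone; median -0.41, camera adjusted p = 3.2e-10; adjusted p = 0.00749 with an estimated correlation). These were NOP16, the nucleolar protein gene NPM1 and NCL, which encodes nucleolin (log2 -0.95, -0.52 and -0.46, adjusted p = 0.0294, 0.016 and 0.0228). With quantile normalization NPM1 and NCL turned to 0.06 and 0.08, and without a filter both calls were lost. Each line alone and the replicate block ended all 3 calls, and median-of-ratios scaling that of NOP16. The list's count was 10 without NALM-6 media 1, 5 without REH CSF 3, 0, 1 and 0 without NALM-6 CSF 1, 2 or 3, 0 with the block, and 22 (1 riser) without both libraries. NOP16 lost its call without any single NALM-6 CSF library or REH media 2 or 3 (2.2e-06 to 0.189 in all), NPM1 without NALM-6 CSF 1 or 3 (2.2e-06 to 0.829), and NCL without NALM-6 media 2 or any single NALM-6 CSF library (1.8e-10 to 0.832). The 30 ribosomal protein genes had a median of -0.71 (camera adjusted p = 1.6e-13; adjusted p = 0.339 with an estimated correlation). Of these limma called 0, with 10 at an unadjusted p under 0.05, 0 called by edgeR and 28 by DESeq2. For 31 genes of oxidative phosphorylation the median was -0.42 (camera adjusted p = 4.2e-09; adjusted p = 0.309 with an estimated correlation). Here limma called 0, with 6 at an unadjusted p under 0.05, 0 called by edgeR and 16 by DESeq2. Both medians moved with NALM-6 media 1. Without it they were -0.27 and -0.16, and 1 oxidative phosphorylation gene fell. Fits without both libraries gave 27 ribosomal protein and 14 oxidative phosphorylation fallers. With median-of-ratios scaling the medians of the MYC, ribosomal protein and oxidative phosphorylation lists were -0.69, -1.01 and -0.71. Of 13 heat shock genes 2 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.24, camera adjusted p = 0.00111; adjusted p = 0.301 with an estimated correlation, 0.657 with quantile normalization, 1.0e-04 to 0.657 in all). The constitutive chaperone gene HSPA8 went from 3298 ± 125 to 2058 ± 23.1 CPM (log2 -0.68, adjusted p = 0.00117). With quantile normalization its log2 value was -0.14 (adjusted p = 0.68), and its call was also lost without a filter and with each line alone (8.2e-09 to 0.68 in all). HSP90AB1 fell by 0.43 on the log2 scale (adjusted p = 0.0325), though with quantile normalization its log2 value was 0.10 (adjusted p = 0.83), and BAG3 rose by 0.52 (adjusted p = 0.00428). The BAG3 call was lost with quantile normalization, edgeR (also without both libraries), DESeq2, and the length and GC correction with the block, over a range of 8.4e-04 to 0.244. The heat shock median was -0.11 without NALM-6 media 1, and 5 fell. There was 1 faller with the block or without NALM-6 media 2 or any single NALM-6 CSF or REH media library. HSP90AB1 lost its call with the block (also with the length and GC correction), no filter, each line alone, and without NALM-6 media 2 or 3 or any single NALM-6 CSF or REH media library (1.0e-12 to 0.83 in all).

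The same comparison in REH concerned a line whose cells carry the ETV6-RUNX1 fusion. ATF3 rose from 8.96 ± 0.191 to 219 ± 3.11 CPM (log2 4.47, SE 0.14, adjusted p = 1.7e-08), and CDKN1A from 124 ± 0.499 to 593 ± 61.8 CPM (log2 2.24, SE 0.11, adjusted p = 4.4e-07). RGS16, which encodes a regulator of G-protein signaling, rose from 0.138 ± 0.0618 to 40.8 ± 3.02 CPM (log2 5.20, SE 0.14, adjusted p = 6.0e-09). PLK1 fell from 281 ± 13.5 to 58.5 ± 2.03 CPM (log2 -2.24, SE 0.19, adjusted p = 1.5e-05).

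FAS and PHLDA3 rose in REH to 46.5 ± 6.45 and 129 ± 37.1 CPM (log2 3.99 and 4.36, adjusted p = 2.3e-06 and 1.6e-06). The smooth muscle actin gene ACTA2, which overlaps FAS on the other strand, went from 0.938 ± 0.151 to 34.4 ± 7.98 CPM (log2 4.17). SULF2, a heparan sulfate sulfatase gene, went from 0.0902 ± 0.0675 to 24.7 ± 2.82 CPM (log2 4.55). GDF15, which encodes a secreted stress cytokine, had 1 read over the 3 media libraries and 25.4 ± 6.08 CPM in CSF, a ratio of 2237 (401 to 88406, counting interval). Among the fallers, PIF1 went from 43.5 ± 1.57 to 3.84 ± 0.505 CPM (log2 -3.20, SE 0.19, adjusted p = 1.3e-06), CDC20 from 305 ± 5.11 to 84.2 ± 15.9 CPM (log2 -1.86, adjusted p = 1.0e-05) and CCNB1 from 248 ± 6.5 to 90.8 ± 9.77 CPM (log2 -1.44, adjusted p = 9.9e-06). PSRC1 fell by 1.46 on the log2 scale, and the cytoskeletal linker gene GAS2L3 went from 11.6 ± 0.0464 to 3.57 ± 1.23 CPM (adjusted p = 2.4e-04 and 2.5e-04). UHRF1, which couples DNA methylation to replication (log2 -1.46, adjusted p = 0.019), and FAM72B, one of a family of near-identical genes (log2 -1.52, adjusted p = 0.0251), fell. UHRF1 lost its call without any single REH media library or REH CSF 3 (log2 -1.28 to -1.49; 3.0e-10 to 0.0724 in all). FAM72B did without any single REH library (log2 -1.42 to -1.58; 8.5e-09 to 0.0824).

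In REH 2144 genes were called, 1899 higher and 245 lower in CSF, with 706 and 51 changed at least 2-fold and 3551 genes at an unadjusted p under 0.05. CSF and media libraries did not overlap for 43.1% of genes, where chance gives 10%. Without NALM-6 media 1, which enters only through the shared spread, the count was 4695. The median over all genes was 0.07, or 0.01 with median-of-ratios scaling, -0.03 with quantile normalization and 0.02 with edgeR. Calls higher and lower in CSF numbered 1462 and 537 with median-of-ratios scaling, 1233 and 839 with quantile normalization, and 1177 and 426 with edgeR, 1855 and 847 with DESeq2, and 1438 and 1242 with the length and GC correction.

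Most measured p53 target, NF-kB target and immediate early genes rose in REH too. Of 21 p53 target genes 17 rose (20 adjusted over the list alone; median 2.11, camera adjusted p = 3.9e-18), including GDF15, PHLDA3, FAS and the mitochondrial reductase gene FDXR (16.1 ± 1.12 to 223 ± 68.3 CPM, log2 3.67, adjusted p = 3.1e-05). Of 18 NF-kB targets 13 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.94, or 1.02 with the 1 member without media reads at its bound; camera adjusted p = 7.0e-07; adjusted p = 0.0597 with an estimated correlation). The risers included the chemokine gene CXCL8 (1.04 ± 0.198 to 12.6 ± 0.523 CPM, log2 2.74), CCL3 (log2 1.66), IER3 (log2 1.66) and the NF-kB subunit gene RELB (log2 1.27). The faller, NFKBIA, which encodes an inhibitor of NF-kB, was named after its value was seen (71.0 ± 1.57 to 46.4 ± 6.46 CPM, log2 -0.61, adjusted p = 0.00898; 0.0708 with the block, 2.2e-07 to 0.0708 in all). There were 2 fallers without NALM-6 media 1. Of 17 immediate early genes 9 rose (11 adjusted over the list alone; median 0.73, camera adjusted p = 7.0e-07; adjusted p = 0.128 with an estimated correlation), such as ATF3, JUN, IER5 (log2 2.09) and the nuclear receptor gene NR4A1 (log2 1.82). Among the quiescence genes 8 of 16 rose (9 adjusted over the list alone; median 0.93, camera adjusted p = 1.6e-04; adjusted p = 0.28 with an estimated correlation), such as BTG2 (17.8 ± 0.343 to 124 ± 1.92 CPM, log2 2.73), BTG1 (log2 1.56) and KLF2 (log2 1.52). Of 27 integrated stress response genes 11 rose (14 adjusted over the list alone; median 0.51, camera adjusted p = 5.1e-06; adjusted p = 0.146 with an estimated correlation), among them SESN2 (log2 2.75), DDIT4 (log2 2.71) and DDIT3, which encodes the stress factor CHOP (log2 2.23, adjusted p = 0.00434). The stress response risers were 17 without NALM-6 media 1. BBC3 (log2 3.53), BAX (log2 1.77) and BAK1 (log2 0.63, named after its value was seen) were among 5 of 14 BCL2 family genes that rose (5 adjusted over the list alone). The BAK1 call was lost without REH media 1 or 3 or REH CSF 2 (0.0512 to 0.0666), and with the block, median-of-ratios scaling, quantile normalization, edgeR, DESeq2 and the length and GC correction (0.0758 to 0.204; 6.7e-05 to 0.204 in all). This list was not called (camera adjusted p = 0.142). Without both libraries, 21 p53, 13 NF-kB, 13 immediate early and 19 stress response genes rose.

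Some mitosis genes fell and some DNA replication genes rose in REH. Of 28 mitosis genes 9 fell (11 adjusted over the list alone; median -0.78, camera adjusted p = 8.4e-11; adjusted p = 0.122 with an estimated correlation), led by PLK1, CDC20 and CCNB1. Of 34 DNA replication genes 11 rose (11 adjusted over the list alone; median 0.30, camera adjusted p = 0.00371; adjusted p = 0.347 with an estimated correlation), such as the origin licensing gene CDC6 (159 ± 1.12 to 313 ± 16.8 CPM, log2 0.97), the chromatin assembly gene CHAF1B (log2 0.87) and the DNA ligase gene LIG1 (log2 0.87). Of 6 histone genes 3 fell (3 adjusted over the list alone; median -0.47, camera adjusted p = 0.0195; adjusted p = 0.251 with an estimated correlation). They included HIST1H2BK (log2 -1.13), and without NALM-6 media 1 the list was at 0.0842 (0.00961 to 0.251 in all). CCNE1 (log2 1.24) was among 3 risers of 16 G1/S genes (3 adjusted over the list alone), which were not called as a list (camera adjusted p = 0.763). There were 6 risers and 2 fallers without NALM-6 media 1. The 1 faller, CCND3 (log2 -0.47), lost its call without any single REH media library or REH CSF 1 or 2, with median-of-ratios scaling and without a filter (4.9e-07 to 0.117 in all). Of 26 MYC and ribosome assembly genes 6 fell (7 adjusted over the list alone; median -0.42, camera adjusted p = 1.6e-08; adjusted p = 0.0066 with an estimated correlation), including MYC itself (284 ± 2.88 to 105 ± 4.4 CPM, log2 -1.43, adjusted p = 4.4e-04) and the dyskerin gene DKC1 (log2 -0.72). The counts without NALM-6 media 1 were 20 mitosis fallers, 18 replication risers and 15 MYC-list fallers, and leaving out both libraries they were 22, 23 and 24. Without REH media 1, 2 or 3, 2, 2 and 3 MYC-list genes were called, and without REH media 1 or 3, 7 replication genes. HSPA8 fell in REH by 0.68 on the log2 scale (adjusted p = 6.3e-04; 0.0699 with quantile normalization, 1.5e-08 to 0.0699 in all). It was among 2 fallers of 13 heat shock genes (2 adjusted over the list alone; median -0.18, camera adjusted p = 0.0133; adjusted p = 0.378 with an estimated correlation). The heat shock list was at 0.39 with quantile normalization and at 0.053 without REH CSF 1 (median -0.051; 7.8e-04 to 0.39 in all). The fallers numbered 5 without NALM-6 media 1, and 1 without any single NALM-6 CSF, REH media or REH CSF library. Ribosomal protein and oxidative phosphorylation genes had medians of 0.20 and 0.18 in REH, with camera directions below the other genes and adjusted p of 0.979 and 0.763. In REH limma called 0 of 30 and 0 of 31, with 0 and 1 at an unadjusted p under 0.05, 0 and 0 called by edgeR, and 0 and 1 by DESeq2. Without NALM-6 media 1, 1 and 3 of them rose, and without both libraries 1 and 4 rose, 3 and 5 fell and the medians were -0.07 and -0.07. Without REH CSF 3 camera called both lists (adjusted p = 0.0466 and 0.0246; 0.00514 to 0.996 and 0.0246 to 0.93 in all).

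With the preset correlation camera called 17 of 39 lists in NALM-6 and 15 in REH. With an estimated correlation 5 held in NALM-6 (p53 targets, immediate early genes, NF-kB targets, MYC and ribosome assembly, histones) and 2 in REH (p53 targets, MYC and ribosome assembly). That adjusted p was the highest over the alternatives of each called list, except heat shock in both lines and autophagy in NALM-6, and the lowest lay between 6.3e-27 and 0.00961.

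**Figure D2:**
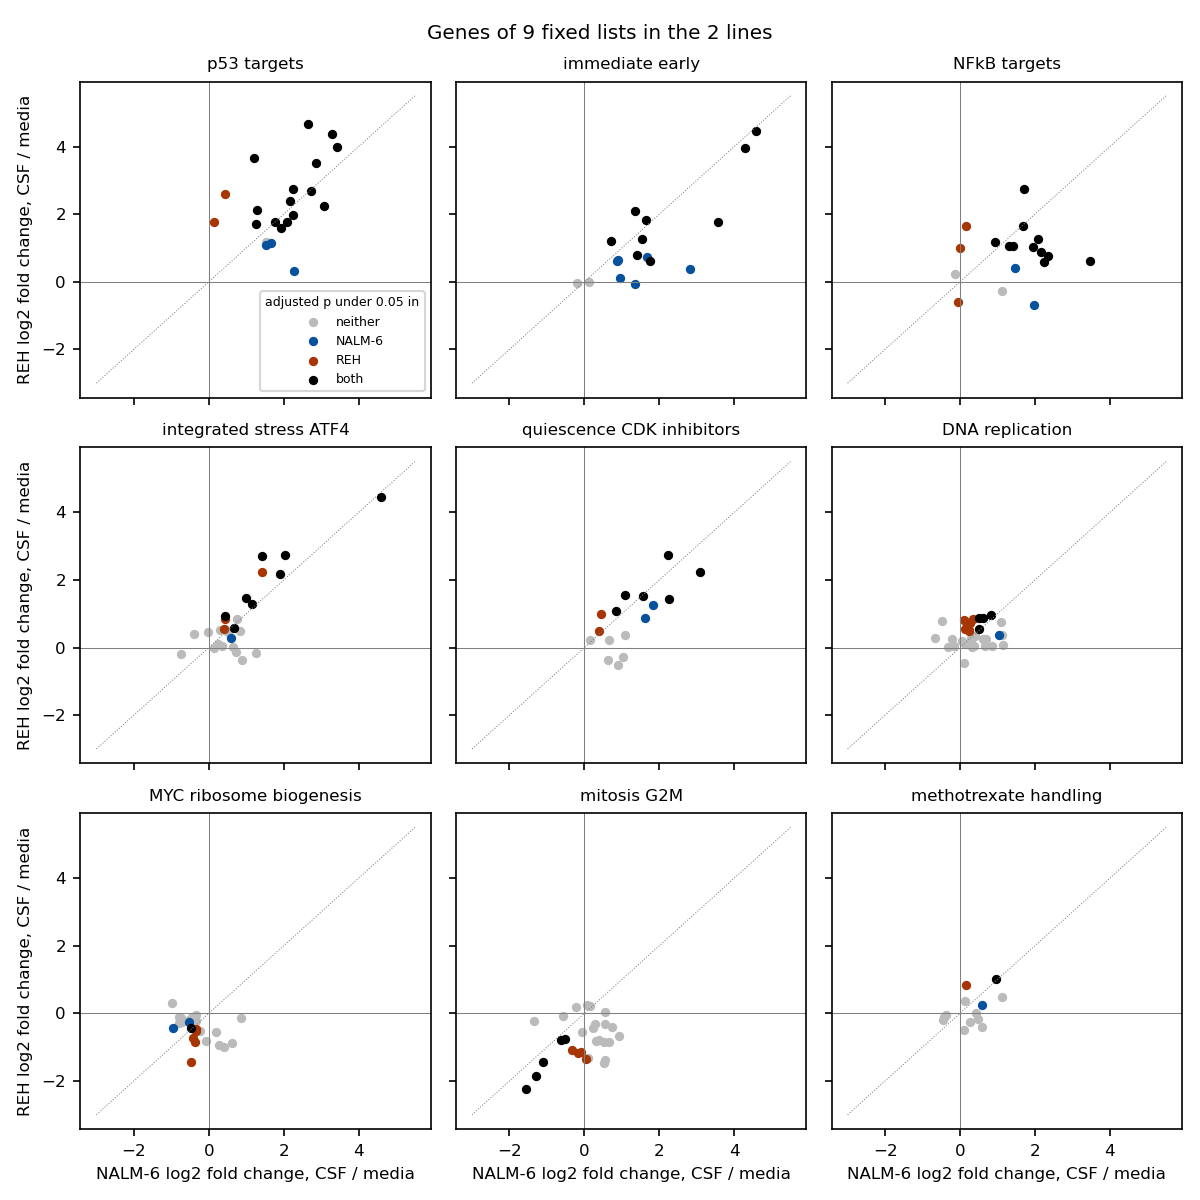
Log2 fold changes (CSF minus media) of the measured members of 9 gene lists, 1 panel per list and 1 point per gene, in NALM-6 (horizontal axis) and REH (vertical axis). Colors show genes called in neither line, NALM-6, REH or both, and the dotted line marks equal change; the p53 targets FAS (3.43 and 3.99) and BBC3 (2.85 and 3.53) lie at the upper right.

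CSF moved 790 genes the same way in both lines, 733 higher and 57 lower, and 2 were called in opposite directions. Independent lists would share 207 and 3.02, but both tests share each gene's variance, which can raise overlap. Ranked by the smaller of the changes in both lines, the leading risers included ATF3, JUN (3.96 in REH, adjusted p = 1.4e-05), FAS, PHLDA3 and BBC3, and the leading fallers were PLK1, CDC20, PIF1, PSRC1, CCNB1 and the histone gene HIST1H2BK (log2 -1.35 and -1.13). Across all 14364 genes, which are not independent replicates, the fold changes of both lines correlated at r = 0.119 (Spearman's rho -0.027). Fits without both libraries gave r = 0.618 and rho 0.608. The shared count was 1610 without NALM-6 media 1, 482 and 483 without NALM-6 CSF 1 or 3, and 391 with the replicate block. Shared genes higher and lower numbered 483 and 126 with median-of-ratios scaling, 338 and 171 with quantile normalization, 490 and 109 with edgeR, 813 and 313 with DESeq2, and 581 and 481 with the length and GC correction.

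**Figure D3:**
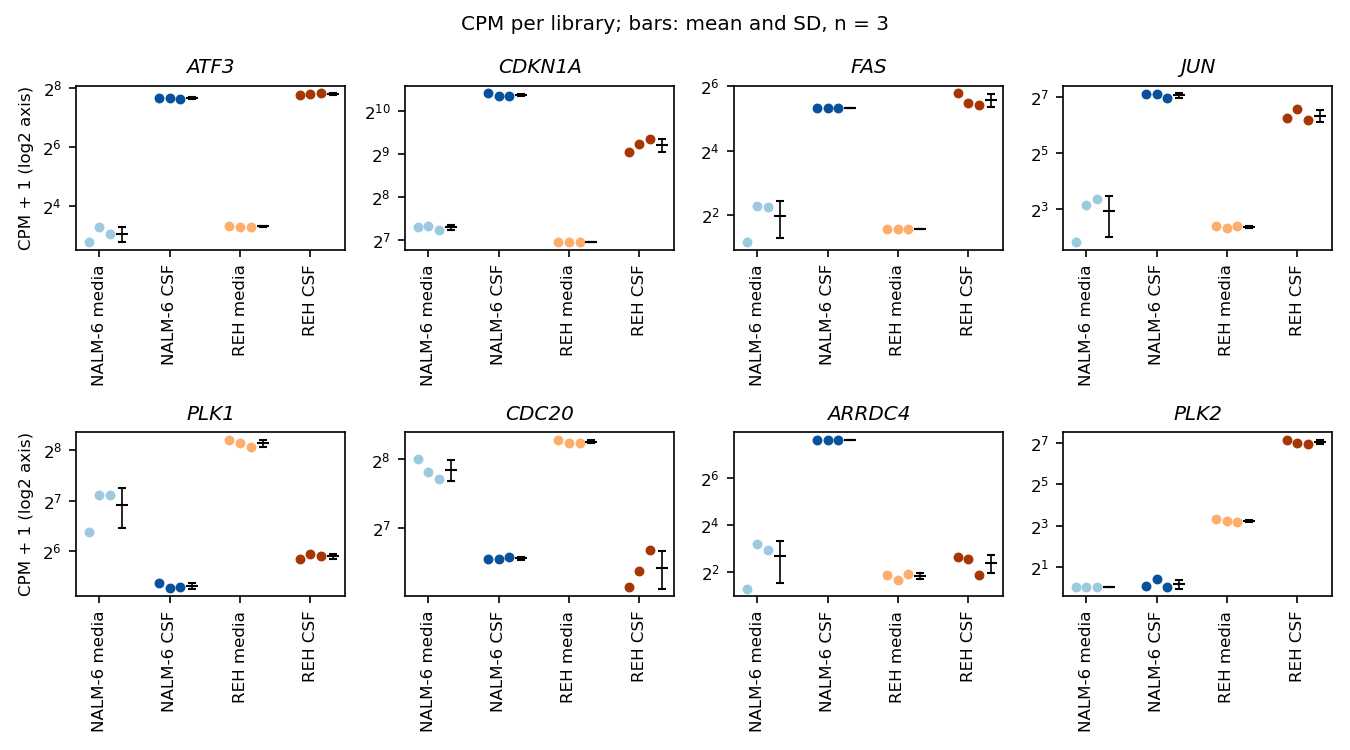
Expression (CPM + 1, log2 axis) of ATF3, CDKN1A, FAS, JUN, PLK1, CDC20, ARRDC4 and PLK2 in each library of NALM-6 and REH in media and CSF, with the mean and SD (n = 3 per group). ATF3 reaches 199 CPM in NALM-6 and 219 CPM in REH in CSF, while ARRDC4 reaches 195 and 4.14 CPM.

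The 13 measured genes of methotrexate targets, transport and metabolism were examined. ABCG2 (ENSG00000118777, chromosome 4, 88090264 to 88231322), whose product exports methotrexate, rose from 12.8 ± 4.27 to 24.8 ± 0.841 CPM in NALM-6 (log2 0.96, SE 0.20, adjusted p = 0.0127) and from 0.907 ± 0.0989 to 2.89 ± 0.17 CPM in REH (log2 1.03, SE 0.20, adjusted p = 0.00568). TYMS, which encodes thymidylate synthase, rose in NALM-6 from 518 ± 47 to 775 ± 17.5 CPM (log2 0.59, SE 0.13, adjusted p = 0.0166), and in REH its log2 value was 0.24 (adjusted p = 0.304). The folate receptor gene FOLR2 rose in REH from 0.415 ± 0.166 to 1.53 ± 0.319 CPM (log2 0.84, adjusted p = 4.4e-04), a level of few reads. The ABCG2 call was lost in NALM-6 with each line alone (0.163) and with the length and GC correction and block (0.0725; 1.1e-05 to 0.163 in all). In REH it was lost with a pseudocount of 5 (log2 0.42, 0.0874; 1.1e-10 to 0.0874).

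A further 9 methotrexate genes were called in neither line by limma with total-read scaling, all libraries and equal weights. The log2 values in NALM-6 and REH were -0.45 and -0.20 for FPGS, which adds the glutamates that retain the drug, 0.14 and 0.37 for GGH, which removes them, and -0.39 and -0.06 for the uptake carrier gene SLC19A1. They were 0.48 and -0.17 for ABCC1, 0.11 and -0.48 for ABCC2, 0.58 and -0.39 for ABCC4 and 0.43 and 0.02 for ABCC5, all exporter genes, and -0.43 and -0.12 for ATIC and 0.28 and -0.26 for GART of purine synthesis. The list was not called (camera adjusted p = 0.909 and 0.898), with 2 risers in each line (2 adjusted over the list alone). TYMS lost its call without NALM-6 CSF 1, 2 or 3, without a filter, and with the block, edgeR, DESeq2, median-of-ratios scaling, each line alone and the length and GC correction and block, over a range of 1.1e-06 to 0.223. Without NALM-6 media 1, 4 of the 13 rose in REH, with GGH at 0.0448 (0.0269 to 0.438 in all) and ABCC2 lower at 0.0435 (0.0435 to 0.702). With edgeR without both libraries ABCC4 turned to -0.28 in NALM-6 (adjusted p = 0.0476; 0.0476 to 0.982 in all), and without NALM-6 media 1 it was -0.19, not called. EdgeR without both libraries also called FPGS (log2 -0.34, adjusted p = 0.00978), ATIC (-0.37, 1.6e-04) and SLC19A1 (-0.34, 0.004) lower in NALM-6. In REH it called FPGS (-0.41, 0.00343), ATIC (-0.31, 5.4e-04), GART (-0.25, 0.00251) and SLC19A1 (-0.25, 0.0217) lower. It called none of these 9 genes higher. ATIC was lower in NALM-6 at 0.045 without NALM-6 media 3 (1.0e-04 to 0.226). With the length and GC correction FPGS was lower in NALM-6 (log2 -0.58, 0.00541) and REH (-0.64, 0.00206), also with the block added. With the correction alone ATIC (0.0197) and SLC19A1 (0.0344) in NALM-6 and GART (0.0262; 0.00251 to 0.926 in all) in REH were lower too. DESeq2 called FPGS, ATIC and SLC19A1 lower in NALM-6 (0.0321, 0.0176 and 0.0264), and quantile normalization ABCC2 lower in REH (0.0488). Array weights called FPGS, ATIC, SLC19A1 and GGH in NALM-6, and ATIC and GART in REH. The range was 0.00465 to 0.29 for FPGS and 0.00307 to 0.285 for SLC19A1 in NALM-6, and 0.00206 to 0.886 for FPGS in REH. In NALM-6 there was 1 riser without any single CSF library and with the block. Without both libraries 3 rose and 2 fell in NALM-6, and 5 rose and 3 fell in REH.

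The interaction asked where the responses differed, and 607 genes were called, 435 with a more positive and 172 with a more negative response in REH (2519 at an unadjusted p under 0.05). PLK2 (ENSG00000145632, chromosome 5, 58453982 to 58460260), a stress-induced kinase gene, rose in REH from 8.42 ± 0.382 to 131 ± 8.78 CPM and stood at 0 and 0.133 ± 0.172 CPM in NALM-6 (difference 3.64, adjusted p = 2.6e-06). ARRDC4 rose in NALM-6, and in REH it went from 2.49 ± 0.3 to 4.14 ± 1.35 CPM with no call (difference -4.63, adjusted p = 0.00107). RGS16 rose in NALM-6 from 88.7 ± 13.2 to 332 ± 12.2 CPM and more steeply from its low level in REH (difference 3.29, adjusted p = 9.4e-06). The retinal reductase gene DHRS3, the mucin gene MUC5AC and the chemokine receptor gene CXCR2 reached 19.1 ± 6.17, 11.5 ± 3.89 and 13.8 ± 2 CPM in REH in CSF and at most 0.457 CPM in NALM-6 (differences 3.17, 3.47 and 3.35); MUC5AC had 3 reads in REH media, a ratio of 340 (116 to 1652, counting interval). In the other direction were TNF, which went from 35 ± 2.07 to 54.4 ± 8.83 CPM in REH (difference -2.85, adjusted p = 3.3e-05), EGR1 (31.3 ± 5.14 to 41.1 ± 3.45 CPM in REH, not called; difference -2.42, adjusted p = 7.8e-04) and TNFRSF9, which encodes the costimulatory receptor 4-1BB. TNFRSF9 had 0 reads in media in both lines and reached 5.08 ± 0.141 CPM in NALM-6, at least 167-fold higher, and 0.131 ± 0.126 CPM in REH, at least 3.82-fold higher (difference -2.43). TNFAIP3, an NF-kB feedback inhibitor gene, went in NALM-6 from 67.1 ± 39.8 to 222 ± 3.39 CPM and stood at 364 ± 12.4 and 230 ± 46.5 CPM in REH (difference -2.65, adjusted p = 0.0426).

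On whole reads edgeR called 116 interaction genes, 59 with a more positive and 57 with a more negative response in REH, DESeq2 303 and 291, and limma 381 and 258 after the length and GC correction. By edgeR, PLK2 turned to -1.06 (adjusted p = 0.476), and MUC5AC, CXCR2, DHRS3 and TNFRSF9 were not called. Over its alternatives the adjusted p spanned 6.3e-09 to 0.866 for PLK2, 6.3e-09 to 0.984 for MUC5AC, 6.3e-09 to 0.744 for CXCR2, 1.1e-07 to 0.401 for DHRS3 and 1.2e-08 to 1 for TNFRSF9. TNFAIP3 lost its call without any single NALM-6 CSF or REH library (0.0662 to 0.107), with the block and with edgeR, over a range of 5.3e-09 to 0.107. The count of interaction genes was 995 without NALM-6 media 1 and 305 with the replicate block. The median difference over all genes was -0.14, or 0.02 with median-of-ratios scaling and -0.02 without NALM-6 media 1.

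By camera 6 lists differed in their response, and none held with an estimated correlation. Ribosomal protein genes had a median difference of 0.95 (adjusted p = 7.3e-07; adjusted p = 0.665 with an estimated correlation), and limma called 0 of 30, with 1 at an unadjusted p under 0.05, 0 called by edgeR and 0 by DESeq2. The median was 0.50 without NALM-6 media 1 and 0.22 without both libraries that stood apart. For oxidative phosphorylation genes the median was 0.62 (adjusted p = 6.1e-04; adjusted p = 0.665 with an estimated correlation), and limma called 0 of 31, with 2 at an unadjusted p under 0.05, 0 called by edgeR and 0 by DESeq2. That median was 0.31 and 0.41 without NALM-6 media 1 or REH CSF 3, and without both it was 0.13 and the call was lost (0.0511; 2.9e-05 to 0.665 in all). Of 28 mitosis genes AURKA, a spindle kinase gene, had a more negative response in REH (difference -0.74; 1 adjusted over the list alone; list median -0.71, adjusted p = 0.00318; adjusted p = 0.648 with an estimated correlation). The AURKA call was lost with the block, median-of-ratios scaling, quantile normalization and edgeR. It was also lost without NALM-6 media 3, any single NALM-6 CSF or REH media library, or REH CSF 1 or 2 (4.6e-05 to 0.215 in all). There were 10 mitosis genes called without NALM-6 media 1, and 16 without both libraries (median -0.38). Of 21 p53 targets TP53I3, GDF15, DDB2 and FDXR responded more in REH and CDKN1A more in NALM-6 (8 and 2 adjusted over the list alone; median 0.22, adjusted p = 0.0423; adjusted p = 0.626 with an estimated correlation). Of the 21, 0 were called by edgeR and 8 by DESeq2. GDF15 had 1 read in the media of each line, and the counting intervals of its ratios overlap (93.3 to 20689 in NALM-6, 401 to 88406 in REH). This list was lost without NALM-6 media 2 or 3, NALM-6 CSF 1, REH media 1, or REH CSF 1 or 2, and with the block. Counts were 10 and 2 without NALM-6 media 1, 5 and 2 without NALM-6 media 3, 3 and 0 with the block, and 16 and 2 without both libraries. The p53 median was 0.50, 0.0075 and 0.038 without NALM-6 media 1, 2 or 3, 0.14 without REH CSF 1 and 0.62 without both libraries. DDB2 lost its call without NALM-6 media 2, any single NALM-6 CSF or REH media library, or REH CSF 2 or 3, and with the block (1.9e-04 to 0.206 in all). CDKN1A lost it with the block (3.9e-06 to 0.293).

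Of 18 NF-kB targets CXCL8, CCL3 and TNFAIP2 had a more positive log2(CPM + 1) difference in REH, the last named after its value was seen, and 6, among them TNF, CD40, TRAF1 and ICAM1, a more negative one (3 and 10 adjusted over the list alone). For CXCL8 the ratio went the other way: it had 0 reads in NALM-6 media and was at least 74.2-fold higher in CSF, against 12.1-fold in REH. By edgeR and DESeq2 its difference was -5.51 and -4.83 (adjusted p = 0.00624 and 0.00386; 1.0e-05 to 0.984 in all). TNFAIP2 lost its call with edgeR (1), DESeq2 (0.657) and the block (0.0576; 1.6e-05 to 1 in all), and CCL3 with edgeR and DESeq2. The median difference was -0.68 (adjusted p = 0.0286; adjusted p = 0.626 with an estimated correlation). This call was lost without NALM-6 media 2 or 3 or REH CSF 1, with the block and with median-of-ratios scaling. Without both libraries 3 and 11 were called. Of 26 precursor B-cell genes the B-cell surface gene MS4A1 had a more negative response in REH (difference -1.69; 1 adjusted over the list alone; list median -0.54, adjusted p = 0.0286; adjusted p = 0.648 with an estimated correlation). The list was lost without NALM-6 media 2 or 3 or REH CSF 1 and with the block. Its count was 5 without NALM-6 media 1 and 2 without REH CSF 3, and 13 (1 in the other direction; list median -0.34) without both libraries. Over their alternatives the adjusted p spanned 3.2e-07 to 0.626 for p53 targets, 2.3e-05 to 0.626 for NF-kB targets and 7.6e-05 to 0.648 for precursor B genes.

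The last comparison set the lines side by side in media, where 5726 genes differed, 3791 higher and 1935 lower in REH (7025 at an unadjusted p under 0.05). PCLO, a synaptic scaffold gene, had 0 reads in NALM-6 and 1275 ± 42.7 CPM in REH, at least 41951-fold higher. IGF2BP1, an RNA-binding protein gene, and IGSF10 were at least 12764-fold and at least 12717-fold higher in REH. Also higher in REH were the leukocyte phosphatase gene PTPRC (0.2 ± 0.158 and 339 ± 17.5 CPM, log2 8.15, SE 0.25, adjusted p = 7.3e-10) and the GABA receptor gene GABRA4 (log2 7.96, adjusted p = 1.5e-11). Higher in NALM-6 were the lymphoid oncogene TCL1A (1381 ± 521 and 0.197 ± 0.0918 CPM, log2 -10.11, adjusted p = 6.6e-11), TAGLN2 (log2 -8.16) and the desaturase gene SCD (log2 -8.14). VPREB1, a surrogate light chain gene, and the metallothionein gene MT1G had 3 and 1 reads in REH media, ratios of 13609 (4656 to 65994) and 28929 (5192 to 1142660, counting intervals). Of genes listed beforehand as telling the lines apart, BIRC7 (at least 901-fold), EPOR (log2 3.24), DSC2 (at least 164-fold; 0.0511 with the length and GC correction and block, 6.4e-14 to 0.0511 in all), TERT (log2 2.07) and ERG (log2 1.49, adjusted p = 0.0013) were higher in REH. ETV6, a partner of the fusion in REH, was at 54.5 ± 22.8 CPM in NALM-6 and 5.07 ± 0.952 CPM in REH (log2 -3.10, SE 0.35, adjusted p = 2.8e-05), and PTPRM was lower in REH (log2 -2.27, adjusted p = 0.00574; 0.144 with the block, 1.7e-13 to 0.144 in all). PAX5 and RUNX1 were not called (log2 0.23 and 0.58, adjusted p = 0.744 and 0.236). Without both libraries PAX5 was lower in REH (log2 -0.50, 1.6e-05; 8.7e-07 to 0.942 in all). The median over all genes was 0.26, or 0.03 with median-of-ratios scaling, -0.03 with quantile normalization and 0.08 without NALM-6 media 1. Genes higher and lower in REH then numbered 3221 and 2551, and 2903 and 3150, with 3061 and 3076 by edgeR, 3460 and 3706 by DESeq2, and 3285 and 3726 after the length and GC correction.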

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

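The comparisons with other splits of the libraries, the correction for length and GC as the whole cause of the deviating libraries, and the leukocyte test were set before their results were seen. The tests of long-transcript loss, of mixed lines, of scaling and trends behind the direction of calls, and of fits without both deviating libraries were chosen afterwards.

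The responses of the lines differed by the interaction test at 607 genes. Of 100 splits of the libraries the real one alone reached that count (1 of 100), and the highest other, which regrouped NALM-6 and kept the REH groups, gave 385. The 790 genes changed the same way in both lines stood against 0 in the highest other of 100 splits (1 of 100). These splits regroup CSF and media within a line, so chance can be excluded only against no response in either line. They do not test whether responses are equal or shared, and no other split could give shared genes because each regrouped line had 0 calls. For the 6 lists that differed between the lines chance cannot be excluded, since 20 of 100 splits gave as many and the highest other gave 12. The lists were ribosomal proteins (adjusted p = 7.3e-07), oxidative phosphorylation (6.1e-04), mitosis (0.00318), NF-kB targets (0.0286), precursor B identity (0.0286) and p53 targets (0.0423), and none held with an estimated correlation (adjusted p = 0.626 to 0.665). The 10 splits possible within a line or between the lines in media are too few for a test. There the real and highest other counts were 1742 and 0 genes in NALM-6, 2144 and 0 in REH, 5726 and 0 between the lines, 17 and 9 lists in NALM-6, and 15 and 15 lists in REH (2 of 10 splits). In NALM-6 the other three splits that part all 3 pairs gave at most 9 lists.

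Single genes had interaction calls, given as the REH minus NALM-6 difference of log2 fold changes. More positive in REH were PLK2 (3.64), MUC5AC (3.47), CXCR2 (3.35), RGS16 (3.29), DHRS3 (3.17), TGFBI (2.55), FDXR (2.47), TP53I3 (2.18), GDF15 (2.04), SDC1 (2.03), ITGB2 (1.97), ACTA2 (1.81) and SULF2 (1.81). Smaller positive differences were those of MS4A7 (1.66), CCL3 (1.51), CSF1R (1.44), DDIT4 (1.28), CXCL8 (1.04), GAD1 (1.04), CCR7 (0.95), DDB2 (0.83), SESN2 (0.72) and FOLR2 (0.67), though the CPM ratios of CXCL8, CCR7 and CSF1R were larger in NALM-6. More negative in REH were ARRDC4 (-4.63), TNF (-2.85), TNFAIP3 (-2.65), TNFRSF9 (-2.43), EGR1 (-2.42), PTPRC (-1.90), GAS2L3 (-1.87), PIF1 (-1.83), FOS (-1.81), MS4A1 (-1.69), TRAF1 (-1.66), CD40 (-1.60), ICAM1 (-1.30), MAP1LC3B (-1.03), CD44 (-0.94), CDKN1A (-0.83) and AURKA (-0.74). The call of SESN2 was lost at 0.056 to 0.118 without any single library but NALM-6 media 1 and REH CSF 3 (4.5e-07 to 0.275 in all). FOLR2 was at 0.0517 to 0.107 without any single library but REH media 1, REH CSF 1 and REH CSF 3 (0.0115 to 1). CCR7 was at 0.0509 to 0.0619 without NALM-6 media 2, NALM-6 CSF 2 or 3 or REH media 1 or 2 (0.00185 to 0.377). With the replicate block the calls of SESN2, FOLR2, CDKN1A, DDIT4, MAP1LC3B, CCR7, CD44, ACTA2, PTPRC, AURKA, TNFAIP3 and DDB2 ended. Besides PLK2, MUC5AC, CXCR2, DHRS3 and TNFRSF9, neither edgeR nor DESeq2 called CCL3, GDF15, MS4A7, CSF1R, GAD1, MS4A1, CCR7, FOLR2, CD44 or CDKN1A. Both called CXCL8 the other way. By edgeR alone the call ended for TGFBI, DDB2, AURKA, MAP1LC3B, ACTA2, TP53I3, PIF1, FDXR and TNFAIP3. Median-of-ratios scaling ended the calls of CDKN1A, AURKA, DDB2, MAP1LC3B and FOLR2, and quantile normalization those of FOLR2, AURKA, DDB2, ICAM1, CCR7 and CD44. The length and GC correction ended those of CD44, FOLR2, SESN2, DDIT4, GAS2L3, PTPRC, DDB2 and CCR7. Adding the block also ended those of SULF2, AURKA, MAP1LC3B, MS4A1, GAD1 and ACTA2. A pseudocount of 0.25 ended those of CXCL8, CCR7, FOLR2, CSF1R, MS4A1, TNFAIP3, DDB2, ACTA2 and SESN2, and one of 5 those of PTPRC and CD40. Over their alternatives the adjusted p spanned 1.0e-05 to 0.984 for CXCL8, 5.0e-06 to 0.765 for CCL3, 6.3e-05 to 0.151 for ACTA2, 2.2e-09 to 0.22 for PTPRC, 2.4e-05 to 0.173 for GAS2L3, 1.2e-05 to 0.0715 for PIF1, 1.9e-07 to 0.0605 for SULF2, 3.9e-06 to 0.293 for CDKN1A, 1.8e-29 to 0.242 for DDIT4, 1.0e-06 to 0.145 for MAP1LC3B, 6.5e-04 to 0.753 for CD44, 3.6e-07 to 0.549 for GDF15, 1.7e-06 to 0.295 for MS4A7, 1.2e-05 to 1 for CSF1R, 3.7e-05 to 0.999 for GAD1, 2.9e-05 to 0.318 for MS4A1, 6.5e-09 to 1 for TGFBI, 1.9e-04 to 0.206 for DDB2, 4.6e-05 to 0.215 for AURKA, 2.5e-05 to 0.0744 for TP53I3, 4.8e-07 to 0.0685 for FDXR, 5.3e-09 to 0.107 for TNFAIP3, 4.9e-06 to 0.0617 for ICAM1 and 1.2e-13 to 0.138 for CD40.

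NALM-6 media 1 and REH CSF 3 stood apart, with an SD over genes of 0.709 and 0.368 from their group means on the log2 scale. A correction for exonic length and GC content left 0.576 in NALM-6 media 1, above the highest of the 8 comparison libraries in other groups (0.196), which argues against these trends as the whole cause. Genes read in REH and not in NALM-6 had a median of 0% of their REH level in that library (0.0226% pooled), against cells of the other line. Loss of reads from long transcripts may be part of the cause, since the deviations correlated across genes with exonic length at -0.481 and -0.544. REH media 1 and NALM-6 CSF 1 also had negative values (-0.315 and -0.218), and no biological explanation was tested.

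Most called genes were higher in CSF, 89.8% in NALM-6 and 88.6% in REH. How far scaling alone accounts for this stays open, since in NALM-6 and REH the shares were 75.9% and 73.1% with median-of-ratios scaling, 74.5% and 73.4% with edgeR, 63.7% and 59.5% with quantile normalization, and 49.6% and 68.7% with DESeq2. Length and GC trends stay open too, at 53.2% and 53.7% after a correction that centres each library, which itself sets the balance, and 86.4% and 82.9% with the library level kept. Leaving out both deviating libraries gave 73.0% and 70.1%, which argues against them alone, but 55.9% and 57.6% with median-of-ratios scaling as well, 59.3% and 53.8% with edgeR and 41.9% and 40.3% with the length and GC correction. Scalings that bring the median of all genes nearer 0 pull the shares toward balance, so scaling cannot be told apart from a difference in RNA content, which was not tested.

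Most measured p53 targets, immediate early genes and NF-kB targets rose in CSF. Leukocytes carried in with the fluid are argued against, as the highest of 5 abundant leukocyte transcripts in any CSF library was CD3E at 0.147 CPM, and S100A8 and S100A9 had 0 reads. Of the monocyte, T and NK markers measured, LYZ and TRAC rose in both lines and CSF1R, MS4A7 and NKG7 in REH. Both deviating libraries are argued against as the cause, since without them 83.9% of the members of the 3 lists together rose in the line with fewer risers (72.2% in its lowest list, NF-kB targets in REH). A response of the cells to the medium stays open as a hypothesis, and what in the medium differs was not tested.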

How the results depend on the processing

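Fits without both deviating libraries (also with edgeR) and the length and GC correction were chosen after the data were seen, and the others were planned. Among the named genes, 312 results kept direction and side of the threshold without an intensity trend (2 lost their call), 308 with a pseudocount of 5, 297 with 0.25, 277 without a low-value filter, 267 with median-of-ratios scaling, 261 with DESeq2, 250 with quantile normalization and 237 with edgeR. With the replicate block 228 did and 86 lost their call. In NALM-6 the block ended the call of TAP1 (0.0657; 2.5e-06 to 0.0932 in all) and of no other gene named here than those for which the block is given. Most causes of changes below were not tested, and the block and fits of each line alone have fewer degrees of freedom.

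In NALM-6 the 1742 genes became 1118 with quantile normalization, 7180 with array weights, 523 with each line alone, 864 with the replicate block, 3381 with DESeq2, 5865 without both libraries and 5793 with edgeR without them. In REH the 2144 became 6561 with array weights, 6586 without both libraries and 6391 with edgeR without them. The 607 interaction genes became 301 with a filter at 5 CPM, 4018 with array weights, 305 with the block, 116 with edgeR, 2198 without both libraries, 261 with the length and GC correction and block, and 1471 with edgeR without both libraries. Between the lines in media the 5726 became 10369, 9628 and 9651 with array weights, without both libraries, and with edgeR without them. The 790 shared genes became 509 with quantile normalization, 3614 with array weights, 391 with the block, 3591 without both libraries and 3559 with edgeR without them. Array weights gave NALM-6 media 1 a weight of 0.0156. Called lists went from 17 to 5 in NALM-6 and from 15 to 2 in REH with an estimated correlation, and to 25 in REH with fry. The 6 interaction lists became 16 without a filter, 10 with quantile normalization, 13 with array weights, 3 with the block, 0 with an estimated correlation, 10 without both libraries, 12 with the length and GC correction and 11 with the block added.

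Leaving out 1 library gave 865 to 2531 genes in NALM-6 (the lowest 3 without a NALM-6 CSF library), 1448 to 4695 in REH and 411 to 995 for the interaction, the highest in both without NALM-6 media 1. It gave 482 to 1610 shared genes. Interaction lists numbered 3 to 15 (15 without NALM-6 media 1, 3 without NALM-6 media 3 or REH CSF 1).

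Directions reversed for HSP90AB1 (0.097), NPM1 (0.056) and NCL (0.077) in NALM-6 with quantile normalization, and for SLC1A2 (-0.093) with the length and GC correction, with or without the block. Interaction values reversed for PLK2 (-1.06), CCR7 (-2.31), CSF1R (-0.19) and CXCL8 (-5.51) with edgeR, for the same 4 genes with DESeq2 (-0.32, -2.48, -0.25 and -4.83), and for CXCL8 (-5.60), PLK2 (-1.05), DHRS3 (-2.25), CCR7 (-2.15) and CD44 (0.14) with edgeR without both libraries; the cause was not tested. In REH same-numbered libraries correlated at -0.46, 0.24 and -0.32, so the numbers do not pair them; with the block REH had 1436 genes, CDC25A, CCND3 and SLC17A7 were at 0.0863, 0.117 and 0.0745, and 2 autophagy genes rose. Depth limits statements on genes near 3 reads per library.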

Other observations

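The test of the ribosomal protein pattern was chosen after the results were seen, as were the fits without both deviating libraries; the lists were fixed beforehand.

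Some adhesion and homing genes rose in both lines. In NALM-6 8 of 20 rose (8 adjusted over the list alone; median 0.60, or 0.40 with median-of-ratios scaling; camera adjusted p = 0.00364; adjusted p = 0.309 with an estimated correlation), with 5 without NALM-6 CSF 1 or 2, and a median of 0.29 without NALM-6 media 1. In REH 6 rose and 1, IL15, fell (log2 -0.40), named after its value was seen (7 and 1 adjusted over the list alone; median 0.35, camera adjusted p = 0.0226; adjusted p = 0.421 with an estimated correlation). These were 12 and 3 without NALM-6 media 1. The IL15 call was lost without REH media 3 or REH CSF 1 or 2, and with edgeR, DESeq2, each line alone and the length and GC correction (0.00272 to 0.659 in all). Leaving out both deviating libraries gave 11 and 1 in NALM-6 and 13 and 3 in REH, where the list's call was lost (0.0643; 0.00272 to 0.421 in all). ITGB2, the beta-2 integrin gene, rose from 31.6 ± 3.73 to 53.3 ± 2.03 CPM in NALM-6 and to 104 ± 12.9 CPM in REH (log2 0.74 and 2.71, adjusted p = 0.00722 and 5.3e-07). Its NALM-6 call was lost with the block (0.0638), median-of-ratios scaling, quantile normalization, edgeR and each line alone (0.0512 to 0.135; 1.5e-05 to 0.135 in all). CCR7, a homing receptor gene, had 2 reads in NALM-6 media and 2.47 ± 0.533 CPM in CSF, a ratio of 122 (33.3 to 1013, counting interval), and rose in REH from 0.434 ± 0.11 to 8.43 ± 1.45 CPM. Of 14 TGF-beta target genes 3 rose in NALM-6 (6 adjusted over the list alone; median 0.37, or 0.09 with median-of-ratios scaling; camera adjusted p = 0.041; adjusted p = 0.301 with an estimated correlation). That call was lost with the block (0.068) and without NALM-6 media 3 (0.112; 0.00635 to 0.301 in all), and 5 rose without NALM-6 media 1 or 3. In REH 6 rose (8 adjusted over the list alone; median 0.60, camera adjusted p = 1.9e-04; adjusted p = 0.0885 with an estimated correlation), or 10 without NALM-6 media 1. Fits without both libraries gave 7 TGF-beta risers in NALM-6 and 10 in REH. ID2 rose in both lines (log2 1.55 and 1.43), and TGFBI in REH from 0.0682 ± 0.0322 to 5.24 ± 0.095 CPM. Of 22 autophagy genes 5 rose in NALM-6 (6 adjusted over the list alone; median 0.30, or 0.03 with median-of-ratios scaling and -0.0030 with edgeR; camera adjusted p = 0.041; adjusted p = 0.37 with an estimated correlation). That call was lost with the block (0.0857) and without NALM-6 media 2 or 3 (0.101, 0.134; 4.0e-05 to 0.447), and 8 rose without NALM-6 media 1. In REH 7 rose (8 adjusted over the list alone; median 0.32, camera adjusted p = 0.00936; adjusted p = 0.348 with an estimated correlation), 4 without any single NALM-6 CSF library, REH media 2 or REH CSF 3, and 3 without REH media 1 or 3. Without both libraries 11 autophagy genes rose in NALM-6 and 12 in REH. MAP1LC3B rose from 100.5 ± 5.6 to 276 ± 5.62 CPM in NALM-6. Of 16 FOXO targets 6 rose and 1 fell in NALM-6 (8 and 1 adjusted over the list alone; median 1.01, camera adjusted p = 0.00268; adjusted p = 0.371 with an estimated correlation), and 4 rose in REH, where the list was not called (median 0.07, or -0.0012 with median-of-ratios scaling and -0.12 with quantile normalization; adjusted p = 0.242). SESN1, which encodes a stress-induced sestrin, rose in both lines, to 71.1 ± 1.9 and 110.3 ± 11.5 CPM (log2 2.17 and 2.39). The FOXO median in NALM-6 was 0.42 without NALM-6 media 1. Both libraries left out gave 12 and 1 in NALM-6 and 6 risers in REH.

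Of 28 interferon response genes 7 rose in REH (7 adjusted over the list alone; median 0.48, camera adjusted p = 0.00813; adjusted p = 0.0865 with an estimated correlation), such as IRF7 (16.1 ± 0.6 to 38.2 ± 9.92 CPM) and TAP1 (log2 0.90). There were 16 without NALM-6 media 1 and 4 without REH media 2 or 3 or REH CSF 2, and 20 without both libraries. In NALM-6 6 rose and the list was not called (median 0.28, -0.05 with quantile normalization; adjusted p = 0.543); 2, 3 and 3 rose without NALM-6 CSF 1, 2 or 3, 1 with the block, and 13 rose and 2 fell without both libraries. Of 26 precursor B genes 4 fell and 2 rose in REH (7 and 2 adjusted over the list alone; median -0.23, camera adjusted p = 1.9e-04; adjusted p = 0.251 with an estimated correlation), with 13 fallers without NALM-6 media 1 and 1 riser without REH media 2 or 3; without both libraries 4 rose and 14 fell. DNTT, the terminal transferase gene, fell from 1161 ± 36 to 590.1 ± 62.1 CPM in REH. In NALM-6 3 rose and 2 fell, and the list was not called (median 0.27, mean 0.19, -0.02 with median-of-ratios scaling, camera below the other genes; adjusted p = 0.352). The NALM-6 counts were 5 and 3 without NALM-6 media 1, with 1 riser without any single NALM-6 CSF or REH media library or REH CSF 2, and at most 1 faller without NALM-6 media 2, any single NALM-6 CSF or REH media library or REH CSF 2. Without both libraries they were 6 and 10, and the list was called (0.0212; 0.0212 to 0.744 in all). Of 7 mature B and plasma cell markers 4 rose and 1 fell in NALM-6, and 2 rose and 1 fell in REH, and the list was not called (adjusted p = 0.061 and 0.391), though SDC1 rose from 2.39 ± 0.439 to 30.0 ± 2.82 CPM in REH. Markers of other cell types, many at low levels, gave 1 and 3 risers of 4 monocyte genes in NALM-6 and REH, and 1 and 2 of 3 T and NK genes. There were 1 and 3 of 4 neuronal genes (ENO2 in both, GAD1 and SLC17A7 in REH), 1 and 0 of 3 glial genes (SLC1A2 in NALM-6) and 1 of 2 endothelial or meningeal genes in both (COL1A1). No choroid plexus or erythroid marker passed the filter. SLC17A7 lost its call without REH media 1, with edgeR, quantile normalization, the length and GC correction, a pseudocount of 0.25 and no filter (0.00102 to 0.584 in all). In NALM-6 ENO2 lost it with quantile normalization (1.4e-08 to 0.117), and SLC1A2 with edgeR, DESeq2, quantile normalization, each line alone and the length and GC correction (0.00108 to 0.87).

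Lists called in neither line, with adjusted p in NALM-6 and REH, were cholesterol synthesis (0.978, 0.477), fatty acid synthesis (0.225, 0.217), cholesterol efflux (0.909, 0.763), the unfolded protein response (0.0801, 0.722), glycolysis (0.141, 0.477), hypoxia (0.742, 0.0608), the TCA cycle (0.155, 0.763), mitochondrially encoded genes (0.485, 0.164) and folate metabolism (0.809, 0.763). The others were purine (0.155, 0.242) and pyrimidine synthesis (0.75, 0.477), nucleoside salvage (0.485, 0.242), iron (0.978, 0.592), metallothioneins (0.127, 0.231), NRF2 targets (0.061, 0.763), selenoproteins (0.0853, 0.359) and class II presentation (0.205, 0.231). Without NALM-6 media 1 the unfolded protein response, glycolysis, purine synthesis and plasma markers were called in NALM-6 (0.0406, 0.0332, 0.0356 and 0.0332; ranges over their alternatives 0.0405 to 0.959, 0.00601 to 0.829, 0.014 to 0.578 and 0.0226 to 0.263). Plasma markers were called without NALM-6 CSF 1 (0.0443), NRF2 targets without NALM-6 CSF 2 (0.0424; 0.0424 to 0.578), and selenoproteins without NALM-6 media 2 or 3 (0.0467, 0.0324; 0.0324 to 0.942). In REH hypoxia genes were called without REH media 2 or REH CSF 3 (0.0476, 0.0451; 0.0186 to 0.587) and mitochondrially encoded genes without REH CSF 1 (0.031; 3.8e-04 to 0.947). Without both libraries glycolysis and purine synthesis were called in NALM-6 (0.0111, 0.014) and purine synthesis in REH (0.0184; 0.0184 to 0.57).

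In NALM-6 the position of ribosomal protein genes below the other genes was tested against NALM-6 media 1 as its cause. Without that library the median was -0.27 (camera adjusted p = 1.9e-06) and that of oxidative phosphorylation genes -0.16 (1.0e-04), which argues against the library as the whole cause; with it the medians were -0.71 and -0.42. With an estimated correlation neither list was called even with it (adjusted p = 0.339 and 0.309).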
